A study of Mus musculus with 21 samples.

How the data were processed

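Expression was measured on Affymetrix Mouse 430 2.0 arrays in 21 samples, 3 in each of 7 groups, from biotin-labelled cRNA made from 2 ug of total RNA, per the labels. The deposited table holds log2 signals from GCRMA, per the submitters' processing notes, and its version is not given in the sources used here. The values show a further step: each probe set is centred on its median over 27 arrays, since at most 13 of its values lie above 0 and at most 13 below, and 79.2% of probe sets hold an exact 0. Of those 27 arrays, 21 are used here, and the 6 others behind each baseline are not used here. The series design describes more groups than the 7 analysed here. Centring removes the level of each gene but leaves differences between arrays untouched, so each value printed for an array is a deviation from that median.

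The table holds 45101 probe sets. The 64 control probe sets were set aside, and of the 45037 others 34945 were assigned to exactly 1 gene symbol, 932 to several and 9160 are unnamed here. The plan made before the data were examined was to keep genes with log2 of 4 or more on at least 3 arrays and to take the probe set with the highest mean. Neither can be done on centred values, so no gene was filtered and each gene was represented by the probe set with the largest SD over the 21 arrays, a choice made after the unit was seen. This gave 18193 genes, 9010 of them with more than 1 probe set. The choice by SD does not use the groups, but it favours the probe set that varies most.

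Genes were compared with limma 3.58.1 in R 4.3.3, by lmFit with 1 mean per group over all 21 arrays, contrasts.fit and eBayes, which left 14 residual degrees of freedom and 1.11 prior degrees of freedom. P values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of 1 or more. There were 9 comparisons of pairs of groups and 1 interaction. Overlap was tested with Fisher's exact test over the genes tested. Gene lists were tested with limma's camera, 2-sided, with a preset correlation of 0.01 and adjustment over 38 lists within each comparison, and again with the correlation estimated for each list and with limma's directional fry. The 38 lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The lists cover the transcription factors and phenotypes of the neuron classes, Hox groups, patterning and signalling responses, and markers of other cell types, and 386 of their 424 genes were tested. Lmx1a, Nkx2-2 and Olig2 are members of the factor lists of their own lines. Their rise there follows from the design, as far as their probe sets read the driven gene, which is not known here. Lists of motile cilium and trophoblast genes were added after the data were seen, with their tests. Beside most lists the number of members called is given over all genes and adjusted over the list alone. For some lists and for the motile cilium list it is given over all genes only.

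The named genes are Lmx1a, Nkx2-2 and Olig2 in every group, the called genes with the largest rises and falls whose arrays do not overlap between groups, all called members of lists on the identity of the cell types compared, and up to 4 called members of other lists. The largest changes number 10 each way in the comparisons set as primary and 5 in the others. Day 14 against day 10, and FGF8 against RA in the Nkx2.2 line, are among the primary ones. The rule on overlap was not applied to the interaction. The text gives a part of them, and some members that were not called are given with their values. Genes that the text names in descriptions of single arrays were chosen after their values were seen.

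The bioC control probe sets separated the arrays into batches A and B, with 9 arrays at -2.75 to -1.27 and 12 at -0.15 to 0.65. The labels name no batch, so this split is inferred from the controls. Fits with the batch as a block (limma) and within a batch were added after the split was seen. Replicate numbers did not pair samples: over 63 pairs of arrays with the same number the mean correlation of residuals was 0.000436, against -0.000378 over 126 pairs with different numbers, so they were not used as a block.

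The test was tried on simulated data: normal noise with each gene's own SD, and changes set in 200 of 18193 genes drawn from those with an SD above the median, in 3 runs. It recovered 49.3% of changes of 1.5 log2 units, 70.6% of changes of 2 and 88.4% of changes of 3. Of its calls 2.35% were false, and limma gave 0 calls in a comparison without changes. The number of arrays limits the precision. Alternatives tried were a replicate block (statmod 1.5.0 is used by the robust moderation), array quality weights, trend and robust moderation, only the arrays compared, the mean of all probe sets, every probe set singly, probe sets without a name suffix, arrays centred on their median, a filter on range, a stricter threshold, the batch fits and leaving out each array. The name suffixes are _a, _g, _s and _x, and a suffix alone does not show that a probe set reads other genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.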

Results

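Gene expression was measured on 21 Affymetrix Mouse 430 2.0 arrays of purified post-mitotic neurons derived from mouse embryonic stem cells. The cells fell into 7 groups of 3 arrays each. In 3 engineered lines a nestin enhancer drove a transcription factor of one neuron class: Lmx1a for midbrain dopaminergic neurons, Nkx2.2 for serotonergic neurons, and Olig2 for somatic motor neurons. The Lmx1a line was sampled at day 10 and day 14 with sonic hedgehog (SHH) and FGF8. The Nkx2.2 line was sampled at day 10 with SHH and either FGF8 or retinoic acid (RA), and the Olig2 line at day 8 with SHH and RA. Wild type cells served as controls at day 10 with FGF8 and at day 8 with RA. The labels of the wild type samples differ on SHH: their titles name it, their source names do not, and their descriptions place the cells in the dorsal midbrain and dorsal hindbrain. If they received none, line and SHH cannot be told apart in the 4 comparisons of a line with wild type cells. The values were deposited as log2 signals centred on each probe set's median, so differences between groups can be read from them and absolute levels cannot. The number of arrays, 3 per group, limits the precision. In what follows each gene is given as a log2 fold change between means of 3 arrays per group, with its standard error. That error comes from 1 variance per gene over all 21 arrays, so it can understate the spread within the groups compared. Slc6a3, for example, had an SD of 1.09 at day 14 of the Lmx1a line, and its change from day 10 has an error of 0.325. With only the arrays compared, 494 of 746 named calls held. Adjusted p values are from limma over 18193 genes.

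The bioC control probe sets split the arrays into 2 apparent hybridization batches, A with 9 arrays and B with 12. The other hybridization controls did not follow this split. Their means ran from -0.26 to 0.49 in batch A, apart from -2.60 in replicate 1 of the Lmx1a line at day 10. In batch B they ran from -0.14 to 0.47. Batch A held all arrays of the Lmx1a line at day 10 and replicates 1 and 2 of the Lmx1a line at day 14, of the Olig2 line and of the FGF8 wild type. Batch B held the rest. Counts with the batch as a block and within a batch stand beside each comparison. Several arrays also stood apart from their replicates, and 3 of them were left out together. Replicate 1 of the Lmx1a line at day 10 had low control signals, and replicate 2 of the FGF8 wild type had low cell cycle genes. Replicate 1 of the Nkx2.2 line under FGF8 had 24 genes over 3 log2 units above the mean of the other 2 replicates. It correlated at 0.54 and 0.347 with replicates 2 and 3, which correlated at 0.28 with each other. Leaving it out therefore kept the least alike pair of that group. Such counts cover only genes on which the other 2 replicates lay close together, so they are hard to compare between arrays. Other arrays stood apart too and were left out 1 at a time only: replicate 3 of the RA wild type had 64 genes over 3 units above the mean of the other replicates, replicate 3 of the Lmx1a line at day 14 had 59 below, and replicate 3 of the Nkx2.2 line under FGF8 had 22 above and 19 below. Replicate 3 of the Nkx2.2 line under RA had 25 above and 4 below, replicate 3 of the Lmx1a line at day 10 had 23 above and 2 below, and replicate 1 of the RA wild type had 1 above and 23 below. Without the first 3 arrays the Lmx1a line against the wild type had 343 genes higher and 325 lower, the Nkx2.2 line under FGF8 against the wild type 411 and 520, day 14 against day 10 548 and 578, and the Lmx1a line against the Nkx2.2 line 537 and 301. The labelling controls were low in all 3 arrays of the Lmx1a line at day 10, at -4.08, -3.79 and -3.93, against -0.44, -1.01 and -0.22 in the FGF8 wild type and -0.34, 0.39 and -1.80 at day 14. Labelling and group therefore cannot be told apart in the 3 comparisons with that group: against the FGF8 wild type, against day 14 and against the Nkx2.2 line.

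The line genes followed the lines. The plotted value of Lmx1a was 8.19 ± 0.13 (mean and SD, n = 3) in its line at day 10, 9.08 ± 0.22 at day 14, and 2.62 ± 0.62 in the FGF8 wild type. Nkx2-2 was at 0.72 ± 0.52 in its line under FGF8 and 1.64 ± 0.20 under RA, against -1.54 ± 0.74 and -0.97 ± 0.20 in the matching wild type groups. Olig2 was at 4.44 ± 0.73 in its line and -0.20 ± 0.04 in the RA wild type. Olig2 also reached 4.89 in replicate 3 of the Lmx1a line at day 10, whose other replicates had 0.58 and 0.91.

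**Figure D1:**
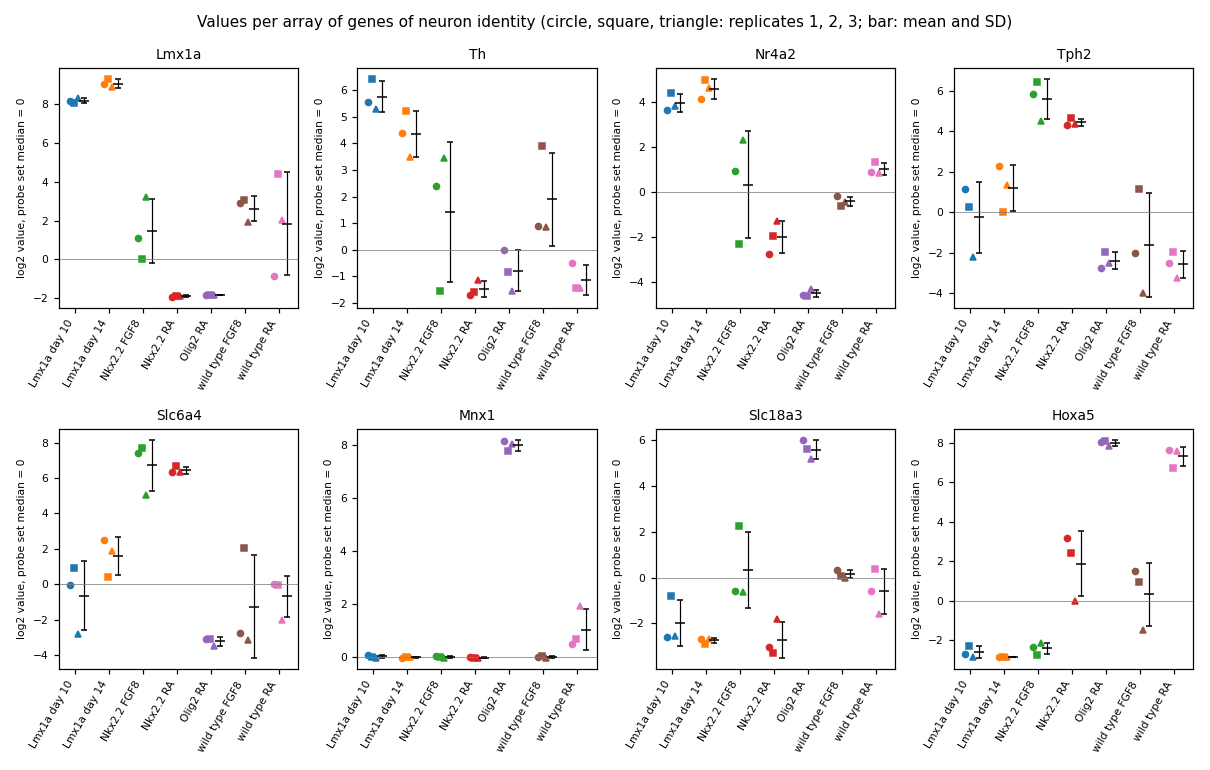
Log2 values of 8 identity genes on each of the 21 arrays by group, with each probe set's median at 0; marker shapes are replicates 1 to 3, and bars give the mean and SD. Lmx1a was highest in the Lmx1a line, Tph2 and Slc6a4 in the Nkx2.2 line, and Mnx1 and Slc18a3 in the Olig2 line.

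The comparison of the Lmx1a line with the FGF8 wild type, both at day 10, asked which genes distinguish neurons made under Lmx1a. Some transcription factors of midbrain dopaminergic neurons were higher, with the floor plate genes Foxa1, Foxa2 and Corin. En2, most dorsal interneuron genes and some genes of the noradrenergic and anterior Hox lists were lower. Of the 11 tested midbrain dopaminergic transcription factors 5 rose, the line gene Lmx1a among them, 1 fell and 5 were not called, against 7 higher and 1 lower adjusted over the list alone. Lmx1a rose by 5.58 ± 0.95 (adjusted p = 0.003), the floor plate factors Foxa2 by 5.15 ± 0.52 (adjusted p = 4.93e-05) and Foxa1 by 5.01 ± 0.45 (adjusted p = 1.98e-05), and Nr4a2, which drives dopaminergic maturation, by 4.40 ± 0.77 (adjusted p = 0.0039). En2 fell by 2.96 ± 0.38 (adjusted p = 0.000424), a call lost within batch A (adjusted p = 0.0659). The list passed the camera test (adjusted p = 5.92e-05; adjusted p = 0.0516 with an estimated correlation). Corin, a surface protease of floor plate cells, rose by 5.28 ± 0.66. Otx2 at 2.75 ± 1.15 (adjusted p = 0.232), Pitx3 at 0.07 and the dopamine transporter Slc6a3 at 0.05 were not called. Of 14 dopaminergic phenotype genes 4 were higher, and 4 adjusted over the list alone (list adjusted p = 0.00878; adjusted p = 0.233 with an estimated correlation). Among them tyrosine hydroxylase, Th, rose by 3.87 ± 1.03 (adjusted p = 0.0435). That call was lost with the batch as a block (adjusted p = 0.0788), within batch A (adjusted p = 0.135) and without any single array of the comparison other than replicate 2 of the wild type, where the adjusted p ranged from 0.0647 to 0.17. Ddc, which completes dopamine synthesis, rose by 3.31 ± 0.67 (adjusted p = 0.0098), a call lost within batch A (adjusted p = 0.107) and without replicate 1 (adjusted p = 0.054) or replicate 3 (adjusted p = 0.0503) of the wild type. Of 11 dorsal and intermediate interneuron genes 9 fell and 10 were lower adjusted over the list alone, with a median change of -3.42 (list adjusted p = 1.18e-15). Lbx1 fell by 5.60 ± 0.34 (adjusted p = 3.66e-07) and Lhx9 fell by 6.10 ± 0.89 (adjusted p = 0.00104). Of 5 noradrenergic genes 2 fell, 3 adjusted over the list alone (list adjusted p = 1.47e-06): Tfap2b fell by 8.61 ± 0.56 and Dbh, the enzyme that makes noradrenaline, fell by 2.87 ± 0.18. Tfap2b had a mean of 6.73 in the RA wild type too, where Dbh was at -0.04, so its fall need not be noradrenergic. Of 10 retinoic acid response genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone (list adjusted p = 0.000436): Cyp26b1, which degrades RA, fell by 4.67 ± 0.43 and Crabp1, which binds it, fell by 3.86 ± 0.46. Of 7 anterior Hox genes in paralog groups 1 to 3, 3 fell and 4 adjusted over the list alone (list adjusted p = 0.000258; adjusted p = 0.157 with an estimated correlation), with Hoxa2 at -4.90 ± 0.72. Of 5 pathway genes that hedgehog signalling represses 3 fell, 4 adjusted over the list alone (list adjusted p = 0.000258; adjusted p = 0.18 with an estimated correlation): Gli3 at -4.90 ± 0.95, Gas1 at -3.52 ± 0.79 and Boc at -2.97 ± 0.71. Within batch A these 3 lost their calls. So did Gas1 without replicate 1 of the Lmx1a line and replicates 1 and 3 of the wild type, at -3.19, -2.94 and -2.84, and Boc without any array but replicate 2 of the wild type, at -2.99 to -2.42. Of 4 hedgehog targets 1 rose, 1 adjusted over the list alone (list adjusted p = 0.0529), Shh at 4.10 ± 0.76 (adjusted p = 0.00524; adjusted p = 0.0512 within batch A). A difference in SHH treatment would move these genes too, so it stays open beside the line. In all, 356 genes were higher and 247 lower, 326 and 211 with the batch as a block, and 182 and 126 within batch A. The counts were 214 and 144 without replicate 1 of the wild type, 453 lower without its replicate 2, and 156 lower without replicate 1 of the Lmx1a line.

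The Nkx2.2 line under FGF8 was compared with the FGF8 wild type, both at day 10, to ask which genes go with the serotonergic line. Genes for making, packing and taking up serotonin rose together, with some serotonergic transcription factors. Of the genes for breaking it down, Maob rose by 5.68 ± 0.34 (adjusted p = 1.86e-07), and Maoa at 2.10 ± 0.68 (adjusted p = 0.0826) was not called. Most dorsal interneuron genes fell, and so did Tfap2b and Dbh of the noradrenergic list. Of 12 serotonergic phenotype genes 9 rose, 10 adjusted over the list alone, with a median change of 5.28 (list adjusted p = 5.87e-20). The serotonin transporter Slc6a4 rose by 7.97 ± 1.22 (adjusted p = 0.00099), tryptophan hydroxylase Tph2, which starts serotonin synthesis, by 7.19 ± 1.05 (adjusted p = 0.000685), Gch1, which makes its cofactor, by 6.79 ± 0.65 (adjusted p = 1.38e-05) and the vesicular monoamine transporter Slc18a2 by 4.88 ± 0.33 (adjusted p = 5.7e-07). Of 8 serotonergic transcription factors 4 rose, 5 adjusted over the list alone (list adjusted p = 1.01e-05), including Gata2 at 3.36 ± 0.54, Gata3 at 3.67 ± 0.65 and Nkx2-2 at 2.27 ± 0.42. Lmx1b, a further factor of serotonergic neurons, was not called at 0.50. The astroglial water channel Aqp4 rose with the serotonin genes, by 4.53 ± 0.44 (adjusted p = 1.79e-05), while of 7 astroglial genes 2 rose and 1 fell, 3 and 1 adjusted over the list alone (list adjusted p = 0.0896). The other that rose was Aldh1l1. Its probe set used here has the suffix _a, and its probe set without a name suffix was at -0.004. The mesenchymal gene Dcn rose by 4.22 ± 0.93 (adjusted p = 0.0123), and no other member of its list was called. Of 14 dopaminergic phenotype genes 3 rose, 3 adjusted over the list alone (list adjusted p = 0.00187; adjusted p = 0.167 with an estimated correlation). They were Gch1, Slc18a2 and Ddc, which dopamine and serotonin neurons share. Of 20 ion channel and receptor genes 4 rose and 1 fell, 6 and 1 adjusted over the list alone (list adjusted p = 0.000137; adjusted p = 0.328 with an estimated correlation), among them the GABA receptor subunit Gabrb1 at 5.62 ± 0.58. Of 11 dorsal and intermediate interneuron genes 9 fell, 10 adjusted over the list alone, with a median of -3.67 (list adjusted p = 1.53e-15). Of 9 dorsal progenitor genes 6 fell, 7 adjusted over the list alone (list adjusted p = 3.04e-07), with Pax3 at -4.43 ± 0.59 and Neurog1 at -4.66 ± 0.68. Tfap2b fell by 8.36 ± 0.56 (adjusted p = 5.33e-07), and of the 5 noradrenergic genes 2 fell, 2 adjusted over the list alone (list adjusted p = 0.000839). Phox2a of that list had means of 1.09 in the line and 1.21 in the wild type. Tfap2b was high in the RA wild type too, at 6.73, where Dbh was at -0.04, so its fall need not be noradrenergic. Of 13 midbrain and isthmus genes 4 fell, against 6 lower and 1 higher adjusted over the list alone (list adjusted p = 0.000826), with En2 at -2.30 ± 0.38 and Gbx2 at -3.20 ± 0.36. Some Hox genes fell too, among them Hoxb6 at -3.57 ± 0.42 (adjusted p = 9.74e-05), Hoxc8 at -4.12 ± 0.77 (adjusted p = 0.00404) and Hoxb9 at -3.30 ± 0.56 (adjusted p = 0.00202). No listed Hox gene was called higher. Of 5 hedgehog-repressed genes 3 fell, 4 adjusted over the list alone (list adjusted p = 2.54e-05; adjusted p = 0.139 with an estimated correlation): Gli3 at -5.03 ± 0.95, Gas1 at -4.44 ± 0.79 and Boc at -3.32 ± 0.71. The call of Boc was lost without replicates 1 and 3 of the wild type (-2.93 and -2.78). Of 4 hedgehog targets 0 were called, 2 higher adjusted over the list alone (list adjusted p = 0.135), and a difference in SHH treatment stays open here as well. The counts were 514 higher and 311 lower, 436 and 229 with the batch as a block, and 250 and 399 within batch B. The count of lower genes rested on single arrays: it was 133 without replicate 1 of the Nkx2.2 line, where 296 were higher, 174 without its replicate 2, and 150, 641 and 169 without replicates 1, 2 and 3 of the wild type.

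The Olig2 line and the RA wild type, both at day 8, were compared for the genes of somatic motor neurons. Several motor neuron transcription factors and cholinergic genes rose, together with enzymes that degrade RA, and most inhibitory and dorsal interneuron genes fell. Of 10 somatic motor neuron transcription factors 5 rose, 7 adjusted over the list alone (list adjusted p = 2.17e-05). Mnx1 rose by 6.97 ± 0.24 (adjusted p = 5.17e-11), Isl1 by 5.39 ± 0.41 (adjusted p = 4.43e-07), Olig2 by 4.64 ± 0.80 (adjusted p = 0.0011) and Lhx3 by 3.00 ± 0.11 (adjusted p = 9.19e-11). Of 8 cholinergic and motor neuron phenotype genes 4 rose, 6 adjusted over the list alone (list adjusted p = 4.08e-07). Choline acetyltransferase, Chat, rose by 4.39 ± 0.28 (adjusted p = 5.51e-08), the receptor Ret by 4.48 ± 0.37 (adjusted p = 1.23e-06) and the intermediate filament Prph by 7.65 ± 0.65 (adjusted p = 1.69e-06). The choline transporter Slc5a7 at 0.55 was not called. Of 10 retinoic acid response genes 6 rose, 6 adjusted over the list alone (list adjusted p = 6.37e-05), led by the RA-degrading Cyp26b1 at 8.23 ± 0.43 and Cyp26a1 at 8.02 ± 0.25, with Dhrs3, which lowers retinal, at 4.92 ± 0.23. A difference in RA exposure between the line and the wild type would move these genes too, and it was not tested. Of 9 FGF response genes 2 rose, Spry4 and Etv4, and 3 adjusted over the list alone (list adjusted p = 0.00403; adjusted p = 0.352 with an estimated correlation). Of 7 GABAergic and glycinergic genes 5 fell, 5 adjusted over the list alone, with a median of -4.29 (list adjusted p = 6.49e-06). The GABA-synthesizing Gad1 fell by 6.22 ± 0.83 and the glycine transporter Slc6a5 fell by 5.36 ± 0.42. Of 11 dorsal and intermediate interneuron genes 7 fell, 7 adjusted over the list alone (list adjusted p = 2.92e-09), with Lbx1 at -7.15 ± 0.34 and Pax8 at -6.00 ± 0.32. Of 8 serotonergic transcription factors 5 fell, 5 adjusted over the list alone (list adjusted p = 0.00213), including Gata3 at -6.91 ± 0.65, which V2b interneurons also use, and Lmx1b at -4.47 ± 0.49, which dorsal interneurons also use. Of 16 synaptic vesicle genes 6 fell, 6 adjusted over the list alone (list adjusted p = 6.49e-06; adjusted p = 0.105 with an estimated correlation), with Sv2a at -2.85 ± 0.25. Of 10 mesenchymal and vascular genes 2 fell, 2 adjusted over the list alone (list adjusted p = 0.0137; adjusted p = 0.352 with an estimated correlation), with Dcn at -3.96 ± 0.93 (adjusted p = 0.0085; adjusted p = 0.305 within batch B). The list was not called with the batch as a block (adjusted p = 0.0868) or without replicate 2 of the wild type (adjusted p = 0.136). Of 7 astroglial genes 2 fell, 2 adjusted over the list alone (list adjusted p = 0.0532). They were Slc1a2 at -2.37 ± 0.43, a call lost within batch B, and Aldh1l1 at -2.83 ± 0.65, whose probe set without a name suffix was at 0.03. The counts were 1001 higher and 883 lower, 711 and 668 with the batch as a block, and 227 and 262 within batch B, which held 1 array of the Olig2 line. Without replicate 1 of the wild type 654 genes were higher.

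The Nkx2.2 line under RA at day 10 was compared with the RA wild type at day 8, so line and day cannot be told apart in it. Serotonin genes were higher, and Hox genes, inhibitory and dorsal interneuron genes and several pan-neuronal and synaptic genes were lower. Of 12 serotonergic phenotype genes 10 rose, 10 adjusted over the list alone, with a median of 6.01 (list adjusted p = 4.47e-10; adjusted p = 0.0667 with an estimated correlation). Ddc rose by 7.27 ± 0.67 (adjusted p = 2.59e-06), Slc6a4 by 7.12 ± 1.22 (adjusted p = 0.000428), Gch1 by 7.09 ± 0.65 (adjusted p = 2.34e-06) and Tph2 by 7.02 ± 1.05 (adjusted p = 0.000146). Nkx2-2 rose by 2.61 ± 0.42 (adjusted p = 0.000277), and Gata3 was not called at 0.62. The astroglial Aqp4 rose by 4.31 ± 0.44 (adjusted p = 6.42e-06) and the myelin gene Mbp by 3.47 ± 0.64 (adjusted p = 0.000776), while of 7 astroglial genes 2 rose and 1 fell (list adjusted p = 0.577). All 6 Hox genes of paralog groups 4 and 5 fell, 6 adjusted over the list alone (median -4.55, list adjusted p = 3.97e-06), with Hoxa4 at -6.44 ± 0.44 and Hoxa5 at -5.46 ± 0.71. Of 6 genes in groups 6 to 8, 5 fell, 5 adjusted over the list alone (list adjusted p = 7.63e-05; adjusted p = 0.113 with an estimated correlation), including Hoxc6 at -4.60 ± 0.51. Of 11 dorsal and intermediate interneuron genes 7 fell, 7 adjusted over the list alone (list adjusted p = 1.17e-07), with Lhx1 at -8.39 ± 0.64 and Lbx1 at -7.17 ± 0.34. Of 7 GABAergic and glycinergic genes 5 fell, 5 adjusted over the list alone (list adjusted p = 0.00047; adjusted p = 0.0543 with an estimated correlation). Of 15 pan-neuronal genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone (list adjusted p = 0.00013; adjusted p = 0.265 with an estimated correlation). The neuronal nuclear protein Rbfox3 fell by 3.44 ± 0.42 and the filament protein Ina fell by 2.65 ± 0.24, while the adhesion molecule Ncam1 rose by 3.05 ± 0.39. Of 16 synaptic vesicle genes 8 fell, 9 adjusted over the list alone (list adjusted p = 0.000739; adjusted p = 0.265 with an estimated correlation), such as Vamp2 at -2.14 ± 0.39. There were 1608 genes higher and 1667 lower, 1589 and 1659 with the batch as a block, and 1287 and 1478 within batch B, which held both groups whole.

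Both comparisons of the Nkx2.2 line with its wild type, which share no array, called the same genes more often than independent calls would. Together they raised 324 genes, where 45.4 were expected (odds ratio 21.8, 2-sided Fisher exact p = 1.4e-216), and lowered 189, where 28.5 were expected (odds ratio 17.2, Fisher exact p = 1.08e-116). Slc6a4, Tph2, Gch1, Ddc and Slc18a2 were among the genes raised in both, and Lbx1 among those lowered in both. There were 5 genes higher under FGF8 and lower under RA, and 4 the reverse, where 47.1 and 27.5 were expected. With the batch as a block 249 were raised and 122 lowered in both, and within batch B 112 and 70. Without replicate 1 of the Nkx2.2 line under FGF8 193 were raised and 84 lowered in both. The lowered count was 120 without its replicate 2, and 101 and 120 without replicates 1 and 3 of the FGF8 wild type. With only the arrays compared in each fit, 90 were raised and 93 lowered in both. Genes are not independent of each other, so these p values overstate the evidence. Both comparisons also share each gene's variance from the fit of all 21 arrays, and unexpressed genes were not left out. The expected numbers are therefore likely too low.

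**Figure D2:**
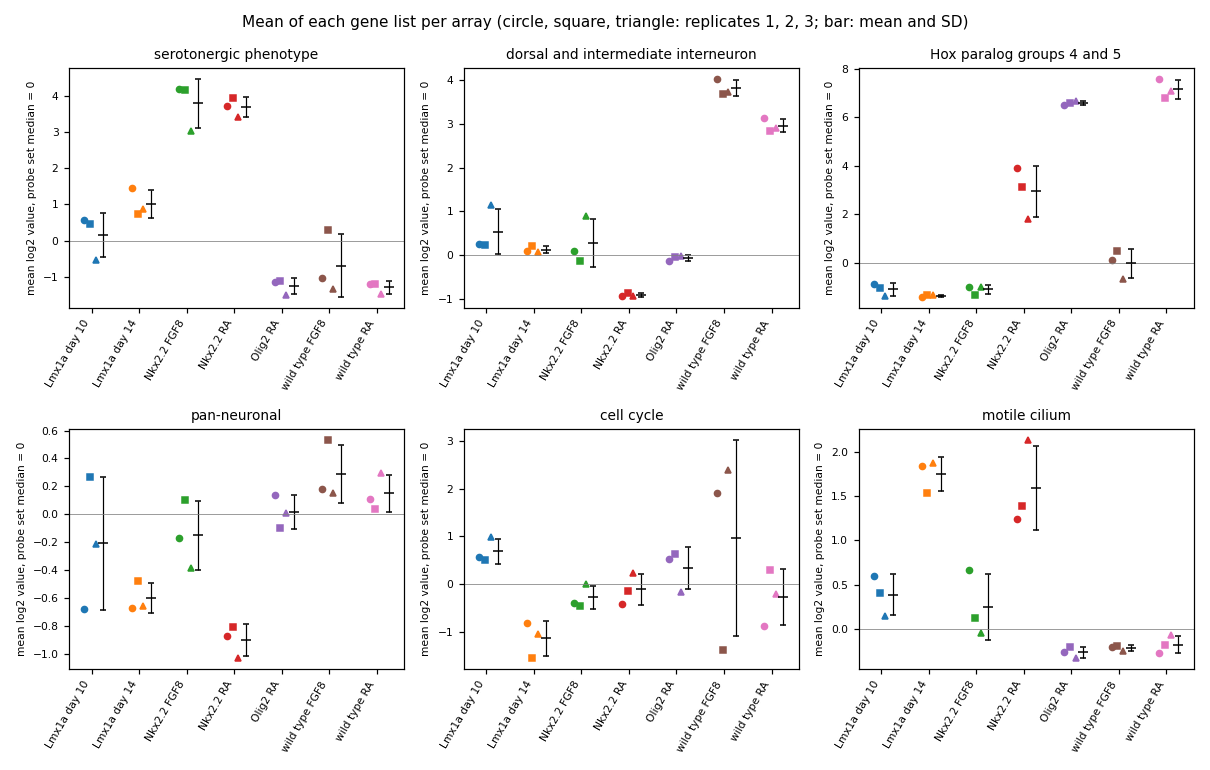
Mean log2 value of the tested genes of 6 lists on each of the 21 arrays by group, with each probe set's median at 0; marker shapes are replicates 1 to 3, and bars give the mean and SD. The serotonergic phenotype list was highest in both groups of the Nkx2.2 line, and the cell cycle list was low in replicate 2 of the FGF8 wild type.

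The Lmx1a line was compared between day 14 and day 10 for genes that change with time in culture. The dopamine transporter gene and several channel and receptor genes were higher at day 14, and Lin28a, Sall4, Isl1 and the neurofilament gene Nefm were lower. The transporter Slc6a3, a mark of mature dopaminergic neurons, rose by 4.26 ± 0.33 (adjusted p = 1.54e-06). Of the genes called against the wild type at day 10, Th at -1.40 ± 1.03 (adjusted p = 0.386), Nr4a2 at 0.63, Foxa2 at -0.07 and Lmx1a at 0.89 were not called between the days. The glutamate receptor subunit Gria2 rose by 1.94 ± 0.38 (adjusted p = 0.00605) and Syn2, a synaptic vesicle protein, by 3.14 ± 0.53 (adjusted p = 0.00244), while the sodium channel Scn9a fell by 2.22 ± 0.37 (adjusted p = 0.00216). Of 20 ion channel and receptor genes 5 rose and 1 fell, 8 and 1 adjusted over the list alone (list adjusted p = 0.024; adjusted p = 0.761 with an estimated correlation). That list was not called without replicates 1 and 3 of day 10 (adjusted p = 0.0546 and 0.0676) or replicate 2 of day 14 (adjusted p = 0.108). Of 16 synaptic vesicle genes Syn2 alone was called (list adjusted p = 0.6). The largest rise with no overlap between the groups was that of Clec3b, which encodes tetranectin, at 6.09 ± 0.28 (adjusted p = 4.03e-09). Lin28a, an RNA-binding protein of early embryonic cells, fell by 5.90 ± 0.83 (adjusted p = 0.000627). The stem cell factor Sall4 fell by 4.37 ± 0.56, Crabp1 by 4.40 ± 0.46, the motor neuron factor Isl1 by 3.25 ± 0.41 (adjusted p = 0.000218), and the neurofilament Nefm by 2.72 ± 0.27 (adjusted p = 2.52e-05). Of 20 cell cycle genes 4 fell, 9 adjusted over the list alone, with a median of -2.06 (list adjusted p = 0.000106; adjusted p = 0.761 with an estimated correlation). Leaving out any 1 of the 6 arrays ended the calls of all 4 members, among them the mitotic kinase gene Bub1 at -3.40 ± 0.90, which then ranged from -3.80 to -3.09. Of 41 motile cilium genes, in a list drawn up after the data were seen, 18 were higher at day 14, with a median of 1.08. The glial and progenitor factor Sox9 rose by 1.82 ± 0.36 (adjusted p = 0.00662), a call lost within batch A (adjusted p = 0.0558). Of 7 astroglial genes 1 was higher, 3 adjusted over the list alone (list adjusted p = 0.264). It was Aldh1l1 at 2.635 ± 0.65 (adjusted p = 0.0232), whose probe set without a name suffix was at -0.06. Of 16 neural progenitor genes 2 were higher and 1 lower (list adjusted p = 0.376). The comparison called 539 genes higher and 233 lower, 524 and 210 with the batch as a block, and 394 and 119 within batch A. The lower count was 485 without replicate 1 of day 10, 128 without replicate 1 of day 14 and 140 without replicate 2 of day 14.

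Under the same line and day, FGF8 was compared with RA in the Nkx2.2 line, for the genes that depend on the patterning factor. Hox genes of paralog groups 4 and 5 were lower under FGF8, the midbrain factor En1 and several neurofilament and cholinergic genes were higher, and the serotonergic phenotype genes were not called. Of the 6 Hox genes in groups 4 and 5, 5 fell, 6 adjusted over the list alone, with a median of -4.47 (list adjusted p = 3.39e-11). Hoxb4 fell by 4.63 ± 0.30 (adjusted p = 1.64e-07), Hoxc4 by 6.05 ± 0.66 (adjusted p = 5.52e-05) and Hoxb5 by 4.91 ± 0.68 (adjusted p = 0.000423). En1 rose by 3.19 ± 0.41 (adjusted p = 0.000243) and Isl1 by 7.20 ± 0.41 (adjusted p = 4.18e-08). Slc6a4 at 0.27 ± 1.22 (adjusted p = 0.916), Tph2 at 1.15 ± 1.05 (adjusted p = 0.667), Gch1 at 0.46 and Gata2 at 0.78 were not called, which does not show that they were equal. Of 8 serotonergic transcription factors 2 were higher, 2 adjusted over the list alone (list adjusted p = 0.229): En1, and Insm1 at 1.49 ± 0.35 (adjusted p = 0.0172). The call of Insm1 was lost without replicate 3 of the FGF8 group (1.27, adjusted p = 0.0744) and without replicate 3 of the RA group (1.30, adjusted p = 0.0592). Of 15 pan-neuronal genes 5 rose and 1 fell, 5 and 1 adjusted over the list alone (list adjusted p = 2.37e-05; adjusted p = 0.388 with an estimated correlation), with Nefm at 3.15 ± 0.27, Tubb3, a neuronal tubulin, at 1.30 ± 0.22, and Ncam1 at -2.99 ± 0.39. Among glial markers Mbp, a myelin protein gene, fell by 3.93 ± 0.64 (adjusted p = 0.00152). The astroglial enzyme Aldh1l1 was at -2.27 ± 0.65 (adjusted p = 0.048), a call that was lost with the batch as a block (adjusted p = 0.06). The call was also lost without any single array except replicate 1 of the FGF8 group, where it ranged from -3.06 to -1.72. The probe set of Aldh1l1 without a name suffix was at 0.02. Of 7 astroglial genes 1 was lower, 1 adjusted over the list alone (list adjusted p = 0.282). Of 8 cholinergic and motor neuron genes 4 rose, 4 adjusted over the list alone (list adjusted p = 0.000567; adjusted p = 0.0843 with an estimated correlation), among them acetylcholinesterase, Ache, at 2.91 ± 0.51. Of 5 visceral motor neuron genes 2 rose, 4 adjusted over the list alone (list adjusted p = 0.00989; adjusted p = 0.0843 with an estimated correlation), with Tbx20 at 5.37 ± 0.82. The counts were 301 higher and 484 lower, 278 and 468 with the batch as a block, and 196 and 262 within batch B, which held both groups whole. Without replicate 1 of the RA group 189 genes were higher.

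The Lmx1a line and the Nkx2.2 line were compared at day 10 with the same factors. Most serotonergic phenotype genes were lower in the Lmx1a line, and some midbrain dopaminergic transcription factors, the line gene Lmx1a among them, were higher. Of 12 serotonergic phenotype genes 9 fell, 9 adjusted over the list alone (median -3.34, list adjusted p = 1.98e-12; adjusted p = 0.0867 with an estimated correlation). Slc6a4 fell by 7.36 ± 1.22 (adjusted p = 0.00231), Tph2 by 5.84 ± 1.05 (adjusted p = 0.00379), and Gata3 by 5.79 ± 0.65 (adjusted p = 0.000123). Nkx2-2 fell by 2.37 ± 0.42 (adjusted p = 0.00372), and so did the astroglial Aqp4, by 4.52 ± 0.44 (adjusted p = 5.51e-05), while of 7 astroglial genes 2 were lower (list adjusted p = 0.55). The other was Aldh1l1, whose probe set without a name suffix was at 0.03. Of 11 midbrain dopaminergic transcription factors 4 rose, 6 adjusted over the list alone (list adjusted p = 0.00757; adjusted p = 0.321 with an estimated correlation), led by Lmx1a at 6.74 ± 0.95 (adjusted p = 0.00072). Of 20 ion channel and receptor genes 5 fell, 8 adjusted over the list alone (list adjusted p = 0.000207; adjusted p = 0.506 with an estimated correlation), including the glutamate receptor subunit Gria4 at -4.30 ± 0.49. Of 16 neuropeptide genes 3 fell, 4 adjusted over the list alone (list adjusted p = 0.00487; adjusted p = 0.178 with an estimated correlation), with the enkephalin precursor Penk at -5.16 ± 0.65. In this comparison 400 genes were higher and 523 lower, and 142 and 348 with the batch as a block. No batch held arrays of both groups, so no within-batch count exists. The higher count was 750, 173 and 239 without replicates 1, 2 and 3 of the Lmx1a line, and 175 and 166 without replicates 1 and 2 of the Nkx2.2 line, where without replicate 1 there were 293 lower.

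The Nkx2.2 line under RA at day 10 was set against the Olig2 line at day 8, where again line and day cannot be told apart. Each line was higher in the genes of its own neuron class. Of 12 serotonergic phenotype genes 10 rose, 10 adjusted over the list alone (median 5.44, list adjusted p = 4.59e-13), with Slc6a4 at 9.67 ± 1.22 and Tph2 at 6.83 ± 1.05. Of 8 serotonergic transcription factors 5 rose, 5 adjusted over the list alone (list adjusted p = 2.83e-05), with Gata3 at 7.53 ± 0.65 and Lmx1b at 5.95 ± 0.49. Of 10 somatic motor neuron transcription factors 7 fell and 1 rose, 7 and 1 adjusted over the list alone (list adjusted p = 2.83e-05). Mnx1 fell by 8.02 ± 0.24 (adjusted p = 4.52e-12) and Lhx3 by 8.01 ± 0.11 (adjusted p = 2.61e-16), and Nkx6-1, a ventral factor that hindbrain progenitors also use, rose by 2.95 ± 0.42. Of 8 cholinergic and motor neuron genes 5 fell, 6 adjusted over the list alone (list adjusted p = 3.12e-07), with the vesicular acetylcholine transporter Slc18a3 at -8.31 ± 0.70 and Chat at -4.37 ± 0.28. Of 10 retinoic acid response genes 7 fell, 7 adjusted over the list alone (list adjusted p = 1.19e-08), with Cyp26b1 at -8.44 ± 0.43. Whether RA exposure differed between the lines was not tested. Of 6 Hox genes in groups 6 to 8, 5 fell, 5 adjusted over the list alone (list adjusted p = 2.09e-06), with Hoxc8 at -7.02 ± 0.77. The counts were 1126 higher and 1262 lower, 936 and 960 with the batch as a block, and 456 and 456 within batch B, which held 1 array of the Olig2 line.

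The RA wild type at day 8 was compared with the FGF8 wild type at day 10 as a view of regional patterning without a driver gene, although factor and day cannot be told apart. Many Hox genes were higher under RA, together with several synaptic genes, and several dorsal progenitor genes were lower. All 6 Hox genes of groups 4 and 5 rose, 6 adjusted over the list alone (median 7.15, list adjusted p = 7.44e-17), led by Hoxb5 at 8.86 ± 0.68 (adjusted p = 1.18e-06) and Hoxa4 at 7.47 ± 0.44 (adjusted p = 6.56e-08). Of 7 genes in groups 1 to 3, 3 rose, 5 adjusted over the list alone (list adjusted p = 4.2e-05; adjusted p = 0.169 with an estimated correlation), with Hoxd3 at 6.12 ± 0.29. Of 6 in groups 6 to 8, 4 rose, 4 adjusted over the list alone (list adjusted p = 4.44e-06; adjusted p = 0.0962 with an estimated correlation). Of 12 in groups 9 to 13, 3 rose, 3 adjusted over the list alone (list adjusted p = 0.00885; adjusted p = 0.39 with an estimated correlation). Of 16 synaptic vesicle genes 8 rose, 9 adjusted over the list alone (list adjusted p = 8.22e-11; adjusted p = 0.0567 with an estimated correlation), including Syn2 at 3.28 ± 0.53 and Sv2a at 2.03 ± 0.25. Of 9 dorsal progenitor genes 5 fell, 6 adjusted over the list alone (list adjusted p = 0.00174; adjusted p = 0.278 with an estimated correlation), with Pax3 at -4.18 ± 0.59. Retinoic acid response genes went both ways. Rarb was at 5.25 ± 0.74 and Tgm2 at 4.08 ± 0.79, while Cyp26b1 was at -3.66 ± 0.43 and Crabp2 at -3.92 ± 0.85. Lhx9, a gene of dorsal midbrain and dorsal interneurons, fell by 7.21 ± 0.89 (adjusted p = 0.000151), and the noradrenergic Dbh fell by 2.96 ± 0.18. Of 10 mesenchymal and vascular genes 1 rose, 1 adjusted over the list alone (list adjusted p = 0.00885; adjusted p = 0.39 with an estimated correlation), Dcn at 4.89 ± 0.93 (adjusted p = 0.00347; adjusted p = 0.0615 within batch B). The list was not called with the batch as a block (adjusted p = 0.0857), without replicate 2 of the FGF8 wild type (adjusted p = 0.093) or without replicate 2 of the RA wild type (adjusted p = 0.128). Of 7 astroglial genes 2 rose, 2 adjusted over the list alone (list adjusted p = 0.0728). They were Aldh1l1 at 2.97 ± 0.65, whose probe set without a name suffix was at -0.03, and Slc1a3 at 3.21 ± 0.79 (adjusted p = 0.016). The call of Slc1a3 was lost with the batch as a block (adjusted p = 0.0836), without replicate 2 of the FGF8 wild type (2.38, adjusted p = 0.0558) and without replicates 2 and 3 of the RA wild type (3.12 and 2.67, adjusted p = 0.0571 and 0.0581). There were 780 genes higher and 566 lower, 519 and 298 with the batch as a block, and 443 and 502 within batch B. The FGF8 wild type decided much of this: without its replicates 1 and 3 there were 505 and 497 higher, and without replicates 1, 2 and 3 there were 295, 869 and 306 lower. Without replicates 1 and 2 of the RA wild type 260 and 279 genes were lower.

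The difference between the effects of the Nkx2.2 line under FGF8 and under RA was tested as an interaction, in which the day of the RA wild type is part of the difference. The serotonin genes did not pass this test: Slc6a4 at 0.85 ± 1.72 (adjusted p = 0.963), Tph2 at 0.18, Gch1 at -0.29 and Ddc at -1.18. Some Hox and inhibitory genes, which were lower in the line under RA, had higher values in the difference. Hox genes fell in the line under FGF8 too, such as Hoxb6 at -3.57 and Hoxc8 at -4.12. Hoxa4 lay near its median in the FGF8 wild type, at -0.20, so its difference mostly restates its fall under RA. In the difference Hoxa4 was at 6.43 ± 0.63 (adjusted p = 2.61e-05), Hoxd3 at 6.10 ± 0.42 (adjusted p = 6.3e-07) and the RA receptor gene Rarb at 6.42. Of 6 Hox genes in groups 4 and 5, 3 were higher, 5 adjusted over the list alone (list adjusted p = 2e-05; adjusted p = 0.0827 with an estimated correlation). Of 7 GABAergic and glycinergic genes 3 were higher, against 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.000974; adjusted p = 0.0827 with an estimated correlation), with Slc6a5 at 4.52 ± 0.60, although the list was not called within batch B (adjusted p = 0.0515). Of 16 synaptic vesicle genes 4 were higher, 10 adjusted over the list alone (list adjusted p = 1.61e-07; adjusted p = 0.0878 with an estimated correlation), with Sv2a at 2.24 ± 0.35. Of 9 dorsal progenitor genes 3 were lower, 6 adjusted over the list alone (list adjusted p = 0.00229; adjusted p = 0.252 with an estimated correlation), with Pax3 at -4.05 ± 0.84. The interaction called 473 genes higher and 323 lower, 342 and 234 with the batch as a block, and 475 and 509 within batch B. It called 799 and 830 without the 3 arrays left out together. Leaving out replicates 1, 2 and 3 of the FGF8 wild type gave 171, 834 and 169 lower genes, and replicates 1 and 3 gave 233 and 242 higher. Without replicates 1 and 3 of the RA wild type the lower counts were 188 and 646, and without replicate 1 there were 310 higher. The higher count was 307 without replicate 1 of the Nkx2.2 line under FGF8 and 315 without replicate 1 under RA.

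**Figure D3:**
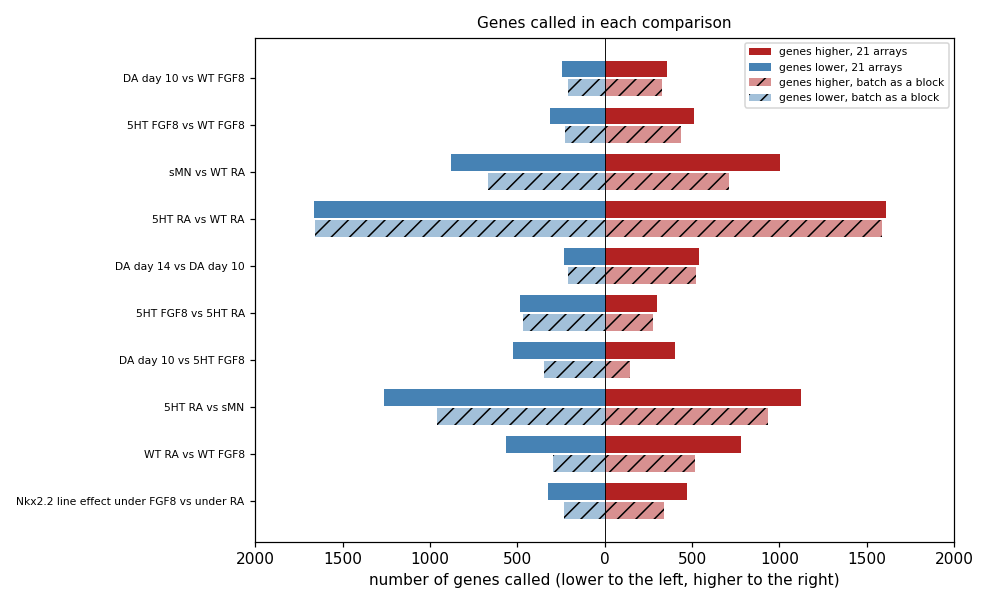
Number of genes called higher (right) and lower (left) in each comparison, from the fit of 21 arrays and with the hybridization batch as a block; DA stands for the Lmx1a line, 5HT for the Nkx2.2 line, sMN for the Olig2 line and WT for wild type. The Nkx2.2 line under RA against its wild type had 1608 and 1667 genes in the first fit and 1589 and 1659 in the second.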

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

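The 3 tests of the cell cycle pattern and the batch fits were chosen only after the results were seen, and the lists of motile cilium and trophoblast genes were drawn up after those patterns were noticed.

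The effect of the Nkx2.2 line differed between FGF8 and RA in a test of the difference itself, with 473 genes higher and 323 lower. Among the genes with the largest differences, Hoxa4 was at 6.43, Rarb at 6.42, Hoxd3 at 6.10, Lhx1 at 5.79 and Pax8 at 5.78, and Anxa1 was at -6.09, Lhx9 at -5.85, Cnmd at -5.47, Lrp2 at -5.17 and Kcnj16 at -5.17. Anxa1 lost its call in 8 of 12 fits that left out 1 array, where it ranged from -7.49 to -4.79, and Lrp2 in 4, namely without replicate 2 of the Nkx2.2 line under FGF8, replicates 1 and 3 of the FGF8 wild type and replicate 1 of the RA wild type, where it ranged from -6.09 to -4.68. The 8 fits for Anxa1 left out replicates 2 and 3 of the Nkx2.2 line under FGF8 and under RA, replicates 1 and 3 of the FGF8 wild type, and replicates 1 and 2 of the RA wild type. Lhx9 and Cnmd were not called within batch B. The difference includes day 8 against day 10 of the wild type cells.

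Chance cannot be excluded for the interaction by regrouping the arrays: 7 of 100 splits, the real one included, called as many genes as the 659 of the real split in a fit of the 12 arrays concerned, and the highest of the others called 2214. All 6 of the other splits with as many calls kept the RA groups whole, and the fewest calls among the other splits that did so was 476, while splits that mixed both arms called at most 4. A split that calls several times the real count points to a structure of the samples, here the large difference between the groups under RA.

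For the 9 comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and in each only 1 split, the real one, reached the real count. The real and the highest other counts, in fits of the compared arrays alone, were 168 and 0 for the Lmx1a line against wild type, 344 and 0 for the Nkx2.2 line under FGF8, 1485 and 1 for the Olig2 line, 2312 and 1 for the Nkx2.2 line under RA, 402 and 0 for day 14 against day 10, 273 and 0 for FGF8 against RA, 124 and 0 for the Lmx1a against the Nkx2.2 line, 1975 and 0 for the Nkx2.2 against the Olig2 line, and 735 and 0 for the wild types.

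Among probe sets without a single gene symbol, which no comparison uses, 52 were higher and 28 lower in the Lmx1a line at day 10 than in the FGF8 wild type, 67 and 31 in the Nkx2.2 line under FGF8, and 125 and 129 in the Olig2 line against the RA wild type.

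Cell cycle genes were low in replicate 2 of the FGF8 wild type, with a list mean of -1.38 against 1.90 and 2.39 in replicates 1 and 3, a fall of 3.52 from the mean of both. A lower signal of the whole array would lower neuronal genes too, but the pan-neuronal mean was higher, a fall of -0.365. The values were already processed with GCRMA, and the median of replicate 2 was 0.065, against 0.006 and -0.028 in replicates 1 and 3. A lower signal may thus have been removed before this test, which cannot decide on it. A batch difference is argued against, since replicates 1 and 2 share batch A and differed by 3.28. A candidate explanation is that replicate 2 held fewer dividing progenitors, since the neural progenitor mean lay 2.2 below the lower of the others. Purification of post-mitotic neurons would act on the same cells, and how it varied between samples was not tested.

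The Lmx1a line at day 10 lay wholly in batch A and the Nkx2.2 line under FGF8 wholly in batch B, yet with the batch as a block the 923 called genes kept a median of 1.06 of their log2 fold change (quartiles 0.958 and 1.17), which argues against this split of the arrays as the whole source of the differences. In the 3 groups that span both batches, each with 1 array in batch B, the difference between batches came to a median of -0.134 (Lmx1a line at day 14), 0.0479 (Olig2 line) and -0.0659 (FGF8 wild type) of that fold change, and limma called 0 genes for the batch term, with 728 at an unadjusted p under 0.05 where chance gives 910. With the block 142 genes were higher and 348 lower, among them 124 of the 400 and 258 of the 523 called without it, whose median shares were 1.04 and 1.08, and standard errors grew by a median factor of 1.35 in each set. The Lmx1a arrays of day 10 also had low labelling controls, and 24.5% of the calls (226 of 923, exact 95% interval 21.7 to 27.4) were also called in the same direction between day 10 and day 14, 46 of them against the FGF8 wild type too. The interval treats genes as independent, which they are not. Both comparisons also share the Lmx1a arrays of day 10, whose noise alone can give calls in the same direction. A labelling effect and the line cannot be told apart by this share. The interval spans the bound set beforehand, and day itself changes genes, so the line difference remains open.

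Motile cilium genes were higher at day 14 than at day 10 in the Lmx1a line: in a list of 41 that left out the genes first noticed, 18 rose, with a median of 1.08 (camera p = 2e-15, p = 0.0282 with an estimated correlation), among them Rsph4a at 4.21 ± 0.21 and Cfap52 at 3.88 ± 0.27. These p values are not adjusted, unlike those of the planned lists, although the list was tested in every comparison. The list was also drawn up after the rise was seen in these arrays, so they overstate the evidence. The batch is argued against, since the median within batch A was 1.02, and so is a single array, since the lowest median with 1 array left out was 0.937. Cells with motile cilia, such as ependymal cells, may be present at day 14, a hypothesis that the list's rise fits, although purification for post-mitotic neurons would be set to remove them. Neurons at day 14 may also raise these genes themselves, which was not tested. Foxj1, the regulator of motile cilia, rose by 2.10 ± 0.59 (adjusted p = 0.0464, not tested with arrays left out) and the glial and progenitor factor Sox9 by 1.82 ± 0.36, while the astroglial list (adjusted p = 0.264) and the neural progenitor list (adjusted p = 0.376) were not called.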

How the results depend on the processing

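The fits by hybridization batch, without the 3 arrays that stood apart, with a filter on range and with probe sets without a name suffix were chosen after seeing the data, and the other alternatives were planned. No gene called over all 21 arrays was called in the opposite direction under any alternative run with 1 value per gene. With every probe set tested singly, another probe set of a called gene was called the opposite way for 1 gene in the Nkx2.2 line under FGF8 against wild type, 3 in the Olig2 line against wild type, 9 in the Nkx2.2 line under RA against wild type and 5 in the Nkx2.2 line under RA against the Olig2 line, and for 0 in the other comparisons (limma). Of 746 named calls, 726 held with the replicate block, 735 with array quality weights, 742 with trend and robust moderation, 494 with only the arrays compared, 681 with the mean of all probe sets, 729 with arrays centred on their median, 559 at an adjusted p under 0.01, 746 with the filter on range and 648 with the batch as a block, and the others were weaker. Of calls that could be tested, 83 of 125 held within batch A, 388 of 563 within batch B, 376 of 449 without the 3 arrays that stood apart, and 4157 of 4824 when 1 array was left out. Where a batch leaves a group 1 array, that array is assumed to vary like the other groups. The replicate block gave 361 genes higher and 239 lower for the Lmx1a line at day 10 against wild type. A stricter threshold lowers the counts by construction, array weights stopped before convergence, and otherwise the cause was not tested. The filter at log2 of 6 and quantile normalization were not run, since the values carry no level. Signal over background cannot be read from centred values, so what low signal hides is unknown.

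Counts higher and lower that moved by over 1.5 times follow. With array quality weights they were 1142 and 1078 for the Lmx1a line at day 10 against wild type, 1029 and 1381 for the Nkx2.2 line under FGF8 against wild type, 1547 higher for the Olig2 line, 1357 and 1124 for day 14 against day 10, 692 and 1086 for FGF8 against RA, 1794 and 1209 for the Lmx1a against the Nkx2.2 line, 1377 and 1422 for the wild types, 1614 and 1888 for the interaction, and 539 and 557 for the overlap. With only the arrays compared they were 111 and 57, 181 and 163, 636 higher, 265 and 137, 118 and 155, 36 and 88, then 161 lower for the wild types, 189 lower for the interaction, and 90 and 93 for the overlap. At an adjusted p under 0.01 they were 169 and 122, 302 and 129, 635 and 548, 301 and 99, 138 and 267, 127 and 278, 405 and 219, 141 and 94, and 187 and 80, in the same order. With the mean of all probe sets the Olig2 line had 577 higher, the wild types 291 lower and the overlap 125 lower. With every probe set tested singly there were 1545 and 1389 for the Olig2 line, 2570 and 2653 for the Nkx2.2 line under RA against wild type, 745 lower for FGF8 against RA, 1896 and 1997 for the Nkx2.2 line under RA against the Olig2 line, and 1176 higher for the wild types, from 45037 probe sets.

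With the batch as a block the counts were 142 and 348 for the Lmx1a against the Nkx2.2 line, 519 and 298 for the wild types, and 122 lower for the overlap. Within batch A they were 182 and 126 for the Lmx1a line at day 10 against wild type and 119 lower for day 14 against day 10. Within batch B they were 250 higher for the Nkx2.2 line under FGF8, 227 and 262 for the Olig2 line, 196 and 262 for FGF8 against RA, 456 and 456 for the Nkx2.2 line under RA against the Olig2 line, 443 higher for the wild types, 509 lower for the interaction, and 112 and 70 for the overlap. Without the 3 arrays that stood apart, 520 were lower in the Nkx2.2 line under FGF8, 578 at day 14, and 301 in the Lmx1a against the Nkx2.2 line, and the interaction had 799 and 830. With an estimated correlation the lists called numbered 4, 6, 6, 2, 0, 1, 0, 7, 1 and 0 in the order of the comparisons of the report, against 15, 14, 11, 12, 4, 4, 8, 14, 14 and 16 with the preset one (camera). With fry they were 19 for the Nkx2.2 line under RA against wild type and 11 for FGF8 against RA. Of the lists called with the preset correlation, fry kept 12, 12, 9, 12, 1, 4, 6, 13, 10 and 11, in the same order of comparisons.

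With 1 array left out the counts higher and lower ranged from 214 to 377 and 144 to 453 for the Lmx1a line at day 10 against wild type, 296 to 603 and 133 to 641 for the Nkx2.2 line under FGF8, 654 to 1280 and 619 to 827 for the Olig2 line, 1303 to 1757 and 1380 to 1813 for the Nkx2.2 line under RA, 390 to 542 and 128 to 485 for day 14 against day 10, 189 to 407 and 329 to 482 for FGF8 against RA, 166 to 750 and 293 to 636 for the Lmx1a against the Nkx2.2 line, 950 to 1109 and 967 to 1478 for the Nkx2.2 line under RA against the Olig2 line, 497 to 762 and 260 to 869 for the wild types, 233 to 682 and 169 to 834 for the interaction, and 193 to 361 and 84 to 228 for the overlap. The lists called ranged from 13 to 16, 12 to 18, 11 to 13, 11 to 12, 1 to 5, 4 to 8, 5 to 12, 13 to 14, 11 to 14 and 10 to 17.

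Of 709 named calls with a probe set without a name suffix, 677 held, 19 were weaker and 13 had the opposite sign on another, flatter probe set, none of these called. Centred values do not show whether the flatter probe sets respond to their genes, so they do not tell which probe set is right. The probe sets of Aldh1l1 and Hoxa10 used in the main fit have the suffix _a. Aldh1l1 was then at -0.003852 for the Nkx2.2 line under FGF8, 0.0261 for the Olig2 line, -0.0609 for day 14 against day 10, 0.01737 for FGF8 against RA, 0.02875 for the Lmx1a against the Nkx2.2 line, -0.01366 for the Nkx2.2 line under RA against the Olig2 line, and -0.03366 for the wild types. Plagl1 was at 0.007222 for the Olig2 line, Slc15a2 at -0.3033 for the Nkx2.2 line under RA against wild type and 0.4138 for FGF8 against RA, and Hoxa10 at 0.01171 for the Nkx2.2 line under RA against wild type, -0.1429 for the wild types and -0.08018 for the interaction.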

Other observations

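The trophoblast list was drawn up after single arrays were examined, and all genes given here per array were chosen after their values were seen.

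Motile cilium genes were also higher in the Nkx2.2 line under RA than in the 3 groups it was compared with, and it was not compared with the Lmx1a line or the FGF8 wild type. Of 41, 23 were higher against the RA wild type, with a median of 1.43 (p = 5.11e-14; p = 0.0359 with an estimated correlation), and 24 against the Olig2 line, with a median of 1.33 (p = 6.97e-19; p = 0.0161 with an estimated correlation), both at day 10 against day 8. Against the Nkx2.2 line under RA, 15 were lower under FGF8 at the same day, with a median of -0.92 (p = 5.06e-18; p = 0.0184 with an estimated correlation). Against the FGF8 wild type, 6 were higher in the Lmx1a line at day 10, with a median of 0.14 (camera p = 1.04e-05; p = 0.196 with an estimated correlation). In the Nkx2.2 line under FGF8 1 was higher, with a median of 0.29 (camera p = 0.000132; p = 0.259 with an estimated correlation). The p values of this list are not adjusted, unlike those of the planned lists.

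The astroglial water channel Aqp4 was higher in the Nkx2.2 line under RA than in the Olig2 line, by 4.64 ± 0.44 (adjusted p = 2.89e-06), as it was in the Nkx2.2 line against both wild types and the Lmx1a line. Of 7 astroglial genes 2 were higher, 3 adjusted over the list alone (list adjusted p = 0.0214; adjusted p = 0.258 with an estimated correlation). The other was Aldh1l1, whose probe set without a name suffix was at -0.01. Midbrain dopaminergic transcription factors differed in sign between measures in that comparison, with a median of -0.01, a mean of 1.39 and an upward test (adjusted p = 0.0214; adjusted p = 0.286 with an estimated correlation), and the call was lost without replicate 3 of the Nkx2.2 line.

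Replicate 1 of the Nkx2.2 line under FGF8 had high values of genes of the placenta and early embryo, led by Rhox6 at 5.70, Ctsj at 5.25, Prl2b1 at 4.66 and Plet1 at 3.81. A hypothesis is that the sample may hold some trophoblast-type cells, and a list of 18 trophoblast genes without those leaders was tested. Of these, 3 lay over 2 log2 units above both other replicates, Krt7 at 3.14, Tfap2c at 2.75 and Phlda2 at 2.53, and 0 lay as far below. The other 15 did not, among them Tpbpa at 2.01 against 0.07 and -0.12, Ascl2 at 0.18 and Hand1 at 0.01, and Krt7, Tfap2c and Phlda2 are also expressed in other epithelial and embryonic cells. Purification of post-mitotic neurons would be set to remove such cells.

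Forebrain genes stood out in single arrays. In replicate 3 of the Nkx2.2 line under FGF8, Six6 was at 7.11, where the other replicates had 0.21 and 0.01, Dlx5 at 6.54 and Lhx8 at 4.56. In replicate 3 of the Lmx1a line at day 10, Six3 was at 7.06, Six6 at 6.45, Fezf2 at 6.18, Lhx8 at 5.41, Eomes at 4.76, Dlx5 at 4.37 and Nkx2-1 at 3.82. Replicate 2 of the FGF8 wild type had 139 genes over 3 log2 units below and 7 above the mean of the other replicates, and it had higher Slc6a4, at 2.07 against -2.74 and -3.12, and Th, at 3.90 against 0.90 and 0.86. Replicate 3 of the RA wild type had 64 genes over 3 units above the mean of the other replicates, and replicate 3 of the Lmx1a line at day 14 had 59 below.

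A single probe set of the Y-linked gene Kdm5d also differed between replicates of a group. It was at 4.48, 4.15 and -0.34 in the Nkx2.2 line under FGF8 and at -0.22, 2.68 and -0.04 in the FGF8 wild type. In the Nkx2.2 line under RA it was at 4.21, 4.22 and 3.97, in the RA wild type at 3.24, 3.43 and 3.75, and in the Lmx1a line at day 14 at 1.16, 1.18 and 1.15. It was at -0.10, -0.04 and -0.28 in the Lmx1a line at day 10 and at -0.08, 0.32 and 0.00 in the Olig2 line. Another probe set of Kdm5d was at 0.03, 0.01 and -0.02 in the Nkx2.2 line under FGF8. The remaining probe set was at 0.24, 0.03 and -0.08 there, at 0.93, 1.05 and 0.18 under RA and at 0.00, 0.16 and -0.08 in the FGF8 wild type. For the Y-linked gene Eif2s3y, 1 probe set was at 0.40, 0.25 and -0.29 in the Nkx2.2 line under FGF8. Another was at 1.42, 1.09 and -0.17 there and, highest in replicate 2 as for Kdm5d, at 0.92, 1.83 and 0.27 in the FGF8 wild type. Nxf3 moved with Kdm5d, at 3.09, 3.58 and -0.30 in the Nkx2.2 line under FGF8 and at -3.13, 2.16 and -3.47 in the FGF8 wild type. The 4 probe sets of the Y-linked gene Uty did not follow Kdm5d in the Nkx2.2 line under FGF8, at 0.39, 0.31 and 0.02, at -0.26, 0.20 and -0.01, at 0.00, 2.06 and 0.24, and at 0.01, 0.04 and -0.23. The probe set of Eif2s3y given first lay between -0.50 and 0.54 on all 21 arrays. These values go against a difference of the whole Y chromosome, as far as the probe sets respond to their genes, which centred values do not show. Whether the cells of origin differed between replicates remains open and was not tested.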
